A study of Mus musculus with 2 samples.

How the data were processed

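Single-cell RNA sequencing was carried out on haematopoietic stem cells (HSCs) sorted from the bone marrow of wild-type C57Bl6 mice, 8 weeks old by the series title. Per the labels, long-term HSCs (LT-HSC) were sorted as LSK cells (lineage negative, Sca-1 positive, Kit positive) that were negative for CD34, CD48 and Flk2 and positive for CD150, and short-term HSCs (ST-HSC) as LSK cells negative for CD34 and positive for CD150 and CD48. There was 1 library per group. The labels name the 10x Genomics 3' kit, which captures polyadenylated RNA in droplets and tags each molecule with a unique molecular identifier (UMI).

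The authors deposited 1 matrix of UMI counts per library, with no normalization, over 32285 genes. Per the submitters' processing notes these counts were made with Cell Ranger 7.2 on the mouse build mm10. Per the file headers the matrices were written by Cell Ranger 7.1.0, and both versions are given because they differ. The deposited barcodes all held at least 500 UMIs in the LT-HSC library and 501 in the ST-HSC library. Cell types were not taken from a deposited annotation. Of the gene IDs, 32158 were found in GENCODE M21 for the same build, from which the 1-based coordinates and gene types were taken.

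Barcodes were kept with at least 1000 genes detected and under 10% of UMIs from mitochondrially encoded genes. Scrublet was run on each library in scanpy 1.11.5, and marked 7 of 2722 LT-HSC cells, or 0.257%. It marked 0 of 6648 ST-HSC cells, so its automatic threshold was taken as failed there, and the 402 cells with scores above the quantile set by the expected rate of 6.07% were left out instead. These 402 cells had a median of 30015.5 UMIs against 12898 in the cells kept, so cycling cells with much RNA may be among them. The analysis kept 2715 LT-HSC cells with 64287832 UMIs and 6246 ST-HSC cells with 98818151 UMIs.

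UMI counts of the kept cells were summed per library and scaled by the library total to CPM. A ratio is ST-HSC over LT-HSC unless the reverse is stated, with the exact conditional binomial (Clopper-Pearson) 95% interval of 2 summed counts. Shares of cells carry exact Clopper-Pearson 95% intervals, CPM values exact Poisson intervals, and a count of 0 a floor of 3 counts. All of these cover counting error only. With 1 library per group there is no replicate error, cells are not replicates, and no p-value was computed, so genes are described by the size of their ratio.

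The genes named were chosen by rules set before the data were examined, as were the gene lists, the cell type markers and the alternatives, except where said otherwise. Genes tested had a mean CPM over both libraries of at least 5. Named were the genes of the sorting gate; the 12 highest and 12 lowest ratios, ranked by the interval bound nearest 1 among genes reaching 20 CPM in a library; in each list, up to 4 members with the largest absolute log2 ratio; 12 fixed genes (Procr, Hlf, Mecom, Hoxb5, Vwf, Cdk6, Mki67, Cdkn1c, Gata1, Pf4, Mpo and Dntt); and the 5 genes with the highest fold in each cluster. One item that these rules name is not reported here. Symbols of unnamed gene models (beginning Gm and a digit, or ending in Rik) were passed over in the second rule, 0 among the higher genes and 1 among the lower. A list member counts as higher at a ratio of at least 1.25 and lower at 0.8 or less, by size. A list stands apart when its median log2 ratio lies outside the central 95% of 10000 random lists of the same size matched on mean expression in 20 bins. Lists needed 5 measured members. Within the HSC-like and the erythroid-like cells the same 12-gene rule was repeated on the summed counts of those cells, which was chosen after seeing the data.

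Both libraries were clustered together on counts per 10000 after log1p, with 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method (leidenalg 0.10.2) at resolution 0.8. No batch correction was applied, since library and group are the same thing here. A cluster was called after a type when at least 3 of its markers were 1.5-fold or more higher and at least 1 stood among the top 50 genes by fold. It stayed unnamed when another type had more markers among the top 10. A cell counted as cycling when the S phase and G2/M phase lists held at least 1% of its UMIs after each cell was thinned to 5000 UMIs, which left out 68 LT-HSC and 259 ST-HSC cells. Effective library sizes for the alternatives came from edgeR 4.0.16 (TMM) and from the median of ratios.

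The ratio interval and the list percentile were tested on simulated data drawn at the depths of these libraries, over 10407 genes. For the comparison of all kept cells, 100% of the 50 genes made 4-fold higher had an interval above 1, as did 100% of the 50 made 2-fold higher, while 6.10% of unchanged genes had an interval that left out 1. By size, all 50 of the first passed the 2-fold limits, but only 11 of the 50 made 2-fold higher and 33 of the 50 set at a ratio of 0.5. The counts were drawn with Poisson error, which the interval assumes, so differences among libraries of a group were not tested. Of 100 unchanged lists of 20 genes, 2 fell outside the central 95% of random lists. These lists were drawn at random from genes simulated independently, so lists of genes that vary together were not tested. The alternatives were other scalings (TMM, median of ratios, a total without mitochondrial and ribosomal protein genes, the mean over cells), other cell filters, other treatments of doublets, other expression filters, leaving out cycling cells, HSC-like cells alone, thinned cells and other settings of the clustering. Symbols given to more than 1 gene ID, 78 in the table, were kept apart by ID.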

Results

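The data are 2 droplet libraries of mouse bone marrow HSCs, 1 labelled LT-HSC and 1 labelled ST-HSC, so each difference between them has no replicate check. LT-HSCs are the stem cells that repopulate marrow for the life of the animal, and ST-HSCs are their descendants with shorter-lived repopulating activity. The library labelled LT-HSC held 2938 barcodes, of which 2715 were kept, with a median of 17529 UMIs and 4768 genes per cell. The library labelled ST-HSC held 7586 barcodes, of which 6246 were kept, with a median of 12898 UMIs and 4155.5 genes per cell. The labels imply a single comparison, of RNA and of kinds of cells between the sorted populations.

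The genes of the sorting gate were read first, as a check of the labels. Slamf1, which encodes CD150, was at 26.6 CPM (95% interval 25.4 to 27.9) in the library labelled LT-HSC and 1.33 CPM (1.11 to 1.57) in that labelled ST-HSC, 20.1-fold lower (16.8 to 24.2), although both gates ask for CD150. Cd34 was at 29.3 CPM in LT-HSC and 243 CPM in ST-HSC, 8.31-fold higher (7.93 to 8.72), although both gates exclude CD34. Flt3, which encodes Flk2, was at 5.54 CPM in LT-HSC and 292 CPM in ST-HSC, 52.7-fold higher (47.5 to 58.7); the stated ST-HSC gate does not mention it. Cd48 was 2.12-fold higher (2.02 to 2.23) in ST-HSC, in the direction of its gate, and 8.10-fold higher (6.203 to 10.7) within HSC-like cells, but at a ratio of 0.277 (0.238 to 0.322) within erythroid-like cells. Ly6a, which encodes Sca-1, and Kit were 1.23-fold and 1.30-fold higher in ST-HSC, and Kit turned to lower, at a log2 ratio of -0.10, without the erythroid-like and megakaryocyte-progenitor-like cells. Slamf1 lies on chromosome 1 from 171767127 to 171801184, Cd34 on chromosome 1 from 194938819 to 194961279, and Flt3 on chromosome 5 from 147330741 to 147400489 (mm10). RNA for Slamf1 and Cd34 in the library labelled ST-HSC thus went against its gate, and every direction given here is between libraries as labelled.

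**Figure D1:**
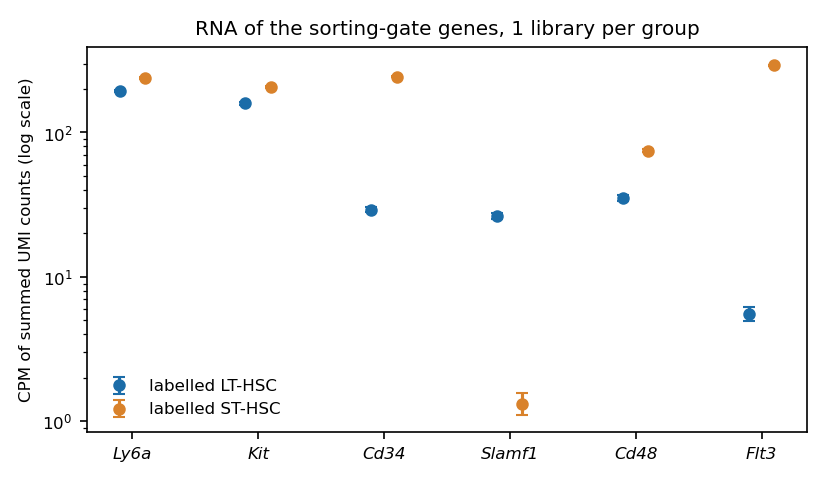
CPM of summed UMI counts on a log axis for the 6 sorting-gate genes in the library labelled LT-HSC (blue) and ST-HSC (orange), with exact 95% Poisson intervals. Slamf1 stands at 26.6 against 1.33 CPM, Flt3 at 5.54 against 292 CPM and Cd34 at 29.3 against 243 CPM.

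Genes of the neutrophil and monocyte lineages and of lymphoid progenitors led the genes higher in the library labelled ST-HSC. Mpo, Elane and Ctsg, which encode granule proteins of neutrophil precursors, were at 319, 296 and 209 CPM in ST-HSC. In LT-HSC they had 5, 11 and 6 UMIs, which puts Mpo at a ratio of 4101 (1757 to 12630). Of the 31515 Mpo UMIs in ST-HSC, 23719 came from cluster 12 of the clustering below, which held 179 of 6246 cells. Mpo was at 4988 CPM there and at 17.5 CPM in the ST-HSC cells of cluster 1, which were HSC-like. Dntt, the terminal transferase of early lymphoid cells, was 321-fold higher (232 to 459), and Ighm, the constant region of the immunoglobulin mu chain, was 116-fold higher (85.6 to 161). Sema3d, Atp8b4, BC035044, Clec12a, Dscam, Ccl3 and Flt3 filled the other places, with ratios from 52.7 for Flt3 to 1371 for Sema3d. Mpo lies on chromosome 11 from 87793581 to 87804413 and Dntt on chromosome 19 from 41029275 to 41059525.

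Platelet and megakaryocyte genes led the genes lower in ST-HSC. Cavin2, a coat protein of caveolae, was at 51.5 CPM in LT-HSC and 0.233 CPM in ST-HSC, 221-fold lower (147 to 349). Pf4, the platelet chemokine, was at 691 CPM in LT-HSC and 16.4 CPM in ST-HSC, 42.1-fold lower (40.1 to 44.3). Treml1 was 29.9-fold lower, Gp5 9.49-fold, Vwf 7.98-fold and Gp9 5.68-fold; Gp5 and Gp9 encode parts of the platelet receptor for the von Willebrand factor that Vwf encodes. Car1, a carbonic anhydrase of erythroid progenitors, was at 3098 CPM in LT-HSC and 396 CPM in ST-HSC, 7.83-fold lower (7.75 to 7.92). Nupr1 was 10.1-fold lower and Apoe 5.92-fold lower. Clec4d (6.02-fold lower) and Kcng2 (5.83-fold lower) turned to higher, at log2 ratios of 0.41 and 0.36, without the erythroid-like and megakaryocyte-progenitor-like cells. Pf4 lies on chromosome 5 from 90772435 to 90773383 and Cavin2 on chromosome 1 from 51289126 to 51302960.

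Of 10407 genes tested, 1109 had a ratio of at least 2 and 302 a ratio of at most 0.5, by size, so that 78.6% of these genes were higher in ST-HSC. The median log2 ratio of all genes was 0.12 and moved to -0.0094 with TMM factors, where the counts were 899 and 416, or 68.4% higher. With the median of ratios they were 888 and 429, or 67.4% higher. Without the erythroid-like and megakaryocyte-progenitor-like cells they were 796 and 625, or 56.0% higher. Gene lists are set against random lists from the same libraries, which carry the same shift.

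Clustering gave 15 clusters, nearly all of them mostly from 1 library, so a cluster may be a library as much as a type. HSC-like cells made 44.6% (42.7 to 46.5) of the library labelled LT-HSC, almost all in cluster 3, and 30.4% (29.2 to 31.5) of ST-HSC, almost all in cluster 1. Cluster 3 was led by Pdzk1ip1, Cdkn1c, Magi2, Sult1a1 and Socs2, and cluster 1 by Hlf, Klf12, Mamdc2, Mill2 and Itsn1. Erythroid-like cells made 32.3% (30.6 to 34.1) of LT-HSC, mainly in clusters 6 and 7, and 5.46% (4.91 to 6.05) of ST-HSC, mainly in cluster 9. Cluster 6 was led by Gm15915, Car1, Zg16, Csrp3 and Clec4d, cluster 7 by Car1, Gm15915, Ermap, Mt1 and Tspo2, and cluster 9 by Hbb-bs, Hba-a1, Hba-a2, Slc25a21 and Rhd. Megakaryocyte-progenitor-like cells made 22.2% (20.7 to 23.8) of LT-HSC and 0.208% (0.111 to 0.356) of ST-HSC. Cluster 8 was led by Pf4, Cavin2, Itga2b, Treml1 and Cd9, and cluster 11 by Pf4, Cavin2 and the histone genes Hist1h2ab, Hist1h3c and Hist1h1b.

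Lymphoid-progenitor-like cells made 14.7% (13.8 to 15.6) of ST-HSC and 0 of 2715 LT-HSC cells, which allows up to 0.110%. Their cluster was led by Wfdc17, Dntt, Sema3d, Arpp21 and Satb1. Neutrophil-monocyte-progenitor-like cells, led by Elane, Ctsg, Mpo, S100a8 and Ms4a3, made 2.87% of ST-HSC and likewise 0 of 2715 LT-HSC cells. Cells in clusters of S phase and of G2/M phase made 20.1% and 19.8% of ST-HSC and 0.184% and 0.405% of LT-HSC. Hells, Uhrf1, Ung and Lig1 were among the leading genes of the S phase cluster. Cluster 4, of G2/M phase, was led by Hist1h2ap, Nusap1, Neil3, Kif11 and Cenpf, and cluster 14, named likewise, by Hist1h2bc, Ccnb2, Ifi27l2a, Knstrn and Cenpa. T-or-NK-cell-like cells, led by Dscam, Ms4a4b, Skap1, Gm2682 and Ikzf3, made 2.16% of ST-HSC, and dendritic-cell-like cells, led by Cybb, S100a4, Ly86, Adam23 and Fgr, made 0.849%; 4 dendritic cell markers stood among the top 50 genes of that cluster and 0 among its top 10. An unnamed cluster led by Plbd1, Naaa, Lgals3, Irf8 and Cxcl9 made 3.44% of ST-HSC and 0.0737% of LT-HSC. The sort and the marker genes set these shares, and the lymphoid-progenitor-like share of ST-HSC was 0% at resolution 0.4 and 7.56% at resolution 1.2.

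**Figure D2:**
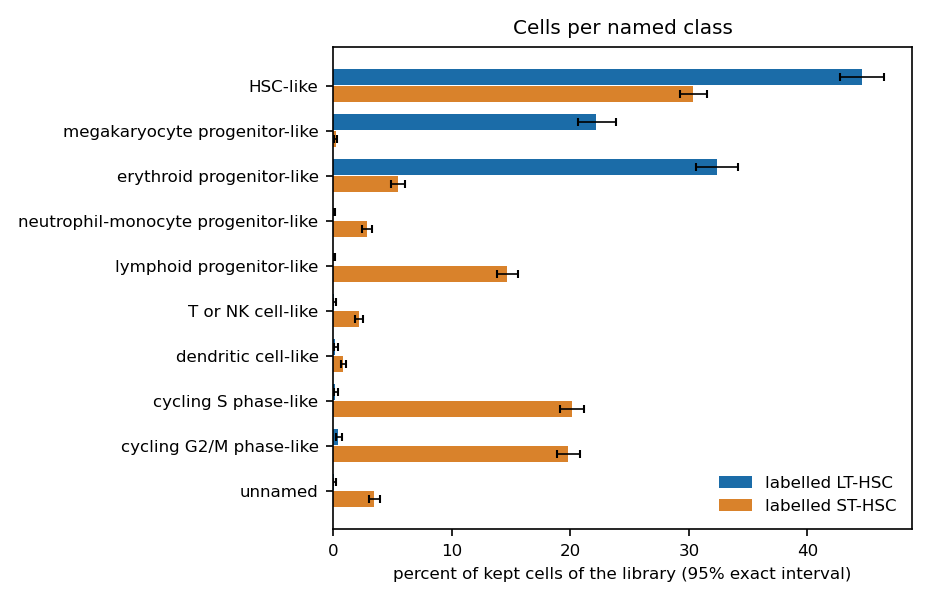
Percent of kept cells in each named class, for 2715 cells labelled LT-HSC (blue bars) and 6246 labelled ST-HSC (orange bars), with exact 95% intervals. Erythroid-like and megakaryocyte-progenitor-like cells stand at 32.3% and 22.2% of LT-HSC, and lymphoid-progenitor-like cells at 14.7% of ST-HSC only.

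Lineage gene lists followed the classes. The markers that named the classes are also members of these lists and were counted in the same cells, so this was partly set beforehand. The megakaryocyte list had a median log2 ratio of -1.87, outside the random range of -0.25 to 0.48, with 14 of 18 measured members lower. Gata1, the erythroid and megakaryocyte transcription factor, was at 72.0 CPM in LT-HSC and 17.0 in ST-HSC. The erythroid list stood at -0.68 (random range -0.22 to 0.41), with 14 of 23 lower, and ranged from -2.86 to -0.43 over the alternatives. Within it the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 were 11.1-fold, 15.4-fold and 18.6-fold higher in ST-HSC; all 3 were lower with every deposited barcode kept, at log2 ratios of -1.28, -0.84 and -1.61, and Hba-a1 and Hba-a2 are near-identical copies whose split is uncertain. The neutrophil-monocyte progenitor list stood at 1.76 (random range -0.29 to 0.44), with 15 of 19 higher. Within HSC-like cells it stood at 0.56 (random range -0.38 to 0.45), with 7 of 12 higher, and over the alternatives it reached 3.51. The lymphoid progenitor list stood at 2.68 (random range -0.25 to 0.55), with 13 of 15 higher, among them Tespa1 at 42.5-fold and Satb1, a chromatin organiser, at 34.0-fold. The basophil, mast cell and eosinophil list stood at 1.97 with 5 of 7 higher. Its granule proteases Prss34 and Mcpt8 were at 14.6 and 13.8 CPM in ST-HSC against 1 and 0 UMIs in LT-HSC, and Hdc and Cpa3 were 11.7-fold and 3.91-fold higher. Within HSC-like cells Prss34 had 0 UMIs in LT-HSC and 2 in ST-HSC, too few for a ratio.

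The dendritic cell list stood at 1.09 (random range -0.48 to 0.52) and MHC class II at 0.94 (random range -0.52 to 0.61), with 6 of 8 and 6 of 7 members higher. Ciita, the class II activator, was 3.98-fold higher, H2-Ab1 2.44-fold, Cd74 2.35-fold, H2-Eb1 1.91-fold and Irf8 15.1-fold, while Cd74 turned to lower, at a log2 ratio of -0.42, within HSC-like cells. Both lists returned inside the random range, at 0.057 and 0.073, without the T-or-NK, dendritic, neutrophil-monocyte and unnamed clusters, an alternative chosen after seeing the data. Lists of other types had under 5 measured members and no median: 3 of mature B or plasma cells, 3 of T or NK cells, 2 of mature neutrophils, 4 of macrophages or monocytes and 3 of endothelial or stromal cells. The sex-linked list had 4; Ddx3y, on the Y chromosome, was at 62.9 and 69.4 CPM and Xist, from the inactive X, at 0.311 and 0.0911 CPM.

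**Figure D3:**
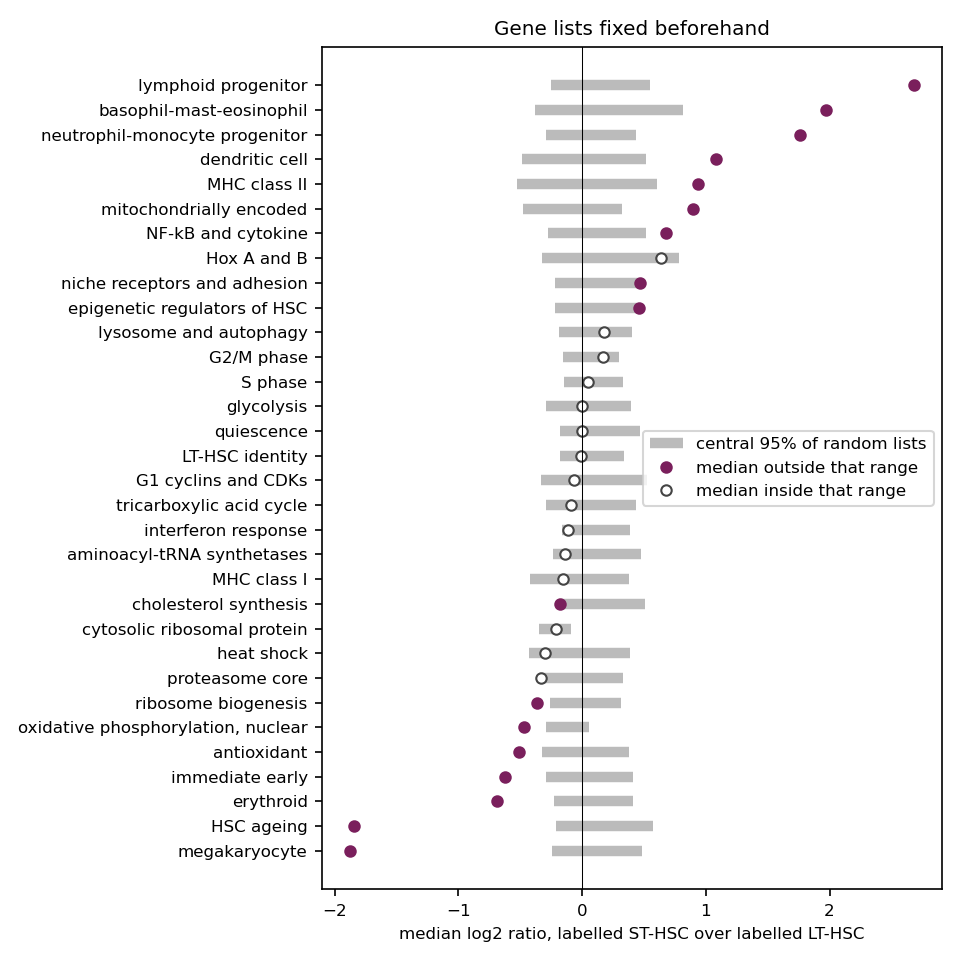
Median log2 ratio, ST-HSC over LT-HSC, of each gene list with at least 5 measured members (points), beside the central 95% of 10000 matched random lists (grey bars). The lymphoid progenitor list lies highest at 2.68 and the megakaryocyte list lowest at -1.87.

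Stem cell genes went both ways. The LT-HSC identity list had a median log2 ratio of -0.012, inside the random range of -0.18 to 0.33, with 14 of 39 measured members higher and 18 lower. Hlf and Mecom, transcription factors of HSCs, were at 141 and 346 CPM in LT-HSC and 457 and 799 CPM in ST-HSC, 3.24-fold and 2.31-fold higher. Procr, which encodes the stem cell surface protein EPCR, was at 24.5 and 24.6 CPM. Hoxb5 was 4.19-fold lower in ST-HSC (3.24 to 5.45), Tcf15 was at 21.3 and 3.98 CPM, Sult1a1 at 11.8 and 1.49 CPM, and Rarb at 8.31 and 1.96 CPM. Without the erythroid-like and megakaryocyte-progenitor-like cells, chosen after seeing the data, the list stood below the random range at -0.98. There the log2 ratio of Mecom was 0.030, that of Hlf 0.29 and that of Procr -1.52. That setting leaves 1211 HSC-like cells among 1234 of LT-HSC but 1897 among 5892 of ST-HSC, so it lowers genes of HSC-like cells by construction. Within HSC-like cells alone the list stood at -0.35, and Hlf was at 423 CPM in LT-HSC and 929 CPM in ST-HSC. Over all kept cells the HSC ageing list was lower, at -1.85 (random range -0.21 to 0.57), with 14 of 17 members lower. Cavin2, Nupr1, Vwf and Sult1a1 led it. The quiescence list stood at -0.0042 with 8 of 22 higher and 7 lower. Cdkn1c, which encodes the cell cycle inhibitor p57, was 2.95-fold lower, Socs2 was at 19.7 and 4.12 CPM, Ndn at 11.0 and 4.04 CPM, and Gfi1, a repressor active in HSCs and granulocytes, at 3.59 and 18.3 CPM.

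Regulators of chromatin and of niche contact were higher on balance in ST-HSC. The epigenetic list stood at 0.46 (random range -0.22 to 0.45), with 12 of 20 higher; Hmga2 was 3.15-fold, Dnmt3a 2.29-fold and Tet1 2.15-fold higher. The niche receptor and adhesion list stood at 0.47 (random range -0.22 to 0.46), with 13 of 21 higher; the cytokine receptors Il1r1 and Il6ra were 11.3-fold and 4.50-fold higher, the integrin Itgal 4.91-fold and the hyaluronan receptor Cd44 2.76-fold. Both lists lay close to the bound and came inside it under some alternatives. The Hox A and B list stood at 0.64, inside its range, but below it at -0.90 without the erythroid-like and megakaryocyte-progenitor-like cells and at -0.34 with no expression filter. Over all kept cells it held Hoxa3, Hoxa7 and Hoxa9 2.76-fold, 1.92-fold and 1.85-fold higher and Hoxa10 at a ratio of 0.712. Without those cells Hoxa7 and Hoxa9 turned to lower, at log2 ratios of -0.15 and -0.11. The lysosome and autophagy list stood at 0.18, inside its range, with the lysosomal protease Ctss 5.30-fold, Npc1 3.28-fold, Psap 2.89-fold and Tfeb 2.69-fold higher.

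Immediate early genes, which respond within minutes to stimulation, were lower in ST-HSC. Their list stood at -0.62 (random range -0.30 to 0.41), with 12 of 20 lower. Ier2 was at 465 CPM in LT-HSC and 138 in ST-HSC, Jund at 528 and 184, Egr1 at 189 and 64.2 and Egr3 at 8.35 and 3.42. The NF-kB and cytokine list was higher, at 0.68 (random range -0.28 to 0.52), with Ccl3 85.6-fold, Ccl4 3.46-fold and Tnf 2.81-fold higher, while the inhibitor Nfkbia was at 283 and 127 CPM. Heat shock (-0.30, with Hspd1 at a ratio of 0.503, Hspe1 at 0.572, Dnajb1 at 0.600 and Hspa1b at 0.680), interferon response (-0.11, with Isg20 at 0.461, Ifi47 at 0.471, Irgm1 at 0.519 and Oas3 at 1.96) and MHC class I (-0.15, with H2-T23 at 0.499, H2-T22 at 0.531, H2-D1 at 0.599 and H2-Q4 at 0.645) lay inside their ranges. Hspa1b turned to higher, at a log2 ratio of 0.86, without the erythroid-like and megakaryocyte-progenitor-like cells. Reads of the class I genes can be split among near-identical copies.

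Mitochondrially encoded and nuclear-encoded genes of respiration moved apart. The mitochondrially encoded list stood at 0.90 (random range -0.48 to 0.32), with 10 of 13 higher; mt-Nd3 was 3.86-fold, mt-Atp6 3.05-fold, mt-Nd2 2.55-fold and mt-Co3 2.502-fold higher. mt-Nd4l, which overlaps mt-Nd4 as mt-Atp8 overlaps mt-Atp6, was at a ratio of 0.637. The nuclear oxidative phosphorylation list was lower, at -0.47 (random range -0.29 to 0.053), with 53 of 78 members lower: Cycs, which encodes cytochrome c, was at 278 CPM in LT-HSC and 139 in ST-HSC, Atp5g1 at 764 and 399, Atp5g2 at 1006 and 563 and Ndufa1 at 201 and 111 CPM. Without the erythroid-like and megakaryocyte-progenitor-like cells that list came inside its range, at -0.045, and Cycs turned to higher, at a log2 ratio of 0.24. Within HSC-like cells the list stood below its range at -0.42, with 49 of 78 lower, and within erythroid-like cells inside it at -0.0040. The median mitochondrial share of UMIs per cell was 1.60% in LT-HSC and 3.47% in ST-HSC, and within HSC-like cells 1.83% and 3.61%.

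**Figure D4:**
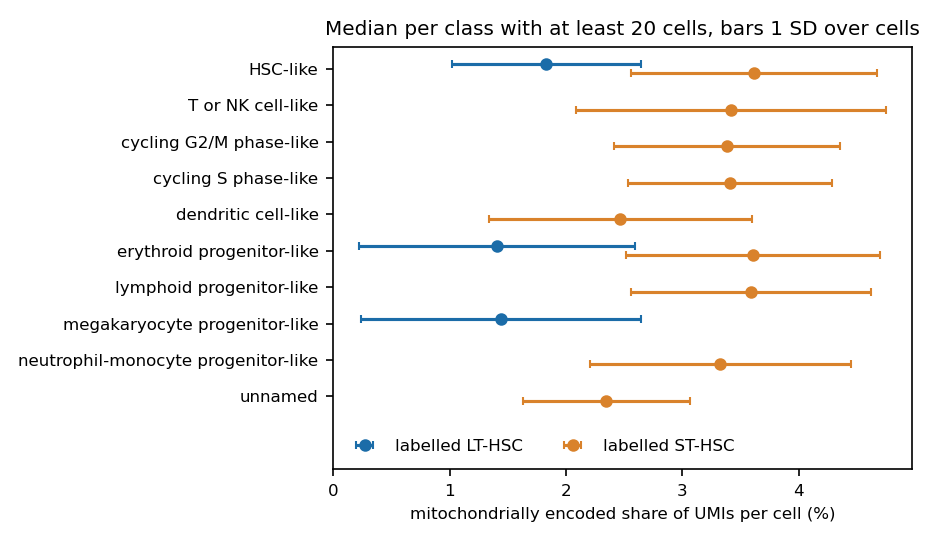
Median percent of UMIs from mitochondrially encoded genes per class with at least 20 cells in the library labelled LT-HSC (blue) or ST-HSC (orange), with bars of 1 SD over cells. HSC-like cells stand at 1.83% and 3.61%, and erythroid-like cells at 1.41% and 3.61%.

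The antioxidant, ribosome biogenesis and cholesterol synthesis lists stood below their random ranges. The antioxidant list stood at -0.51 (random range -0.33 to 0.38), with 12 of 21 lower; the peroxiredoxin Prdx6 was at 731 and 309 CPM, Gclm, of glutathione synthesis, at 263 and 129, Gstm5 at 106 and 45.6 and Nqo1 at 14.9 and 5.15 CPM. Ribosome biogenesis stood at -0.36 (random range -0.26 to 0.32), with 20 of 32 lower; Nop16 was at 104 and 46.7 CPM, Gar1 at 189 and 93.6, Nop10 at 708 and 354 and Nip7 at 112 and 56.0 CPM. It stood at 0.023 without the erythroid-like and megakaryocyte-progenitor-like cells. Cholesterol synthesis stood at -0.18, just below its bound of -0.16, with 6 of 18 members lower and 3 higher, among them Idi1 at 47.4 and 25.3 CPM, Sqle at 26.3 and 16.4, Fdps at 85.3 and 59.1, and Srebf2 1.67-fold higher. Inside their ranges lay glycolysis (-0.0019, with Pdk1 2.76-fold, Pfkp 1.95-fold and Pkm 1.83-fold higher and Ldha at a ratio of 0.473), the tricarboxylic acid cycle (-0.087, with Idh3a at 0.549, Idh3b at 0.576, Fh1 at 0.584 and Sdhb at 0.597) and the proteasome core (-0.33, with Psmb3 at 0.636, Psma3 at 0.667, Psmc5 at 0.674 and Psmb2 at 0.679). Psmb3 was at a log2 ratio of 0.0089 without the erythroid-like and megakaryocyte-progenitor-like cells, and Pkm turned to lower, at -0.15, within HSC-like cells. Also inside theirs were the aminoacyl-tRNA synthetases (-0.14, with Cars at 1.81, Aars at 1.32, Tars at 0.736 and Nars at 0.765) and the cytosolic ribosomal proteins (-0.21, with Rps29 at 1.57, Rps26 at 0.648, Rpl7l1 at 0.653 and Rpl9 at 0.655).

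Within HSC-like cells (mostly cluster 3 of LT-HSC against cluster 1 of ST-HSC) many differences stood with the erythroid-like and megakaryocyte-progenitor-like cells set aside. Of 10629 genes tested there, 629 had a ratio of at least 2 and 375 of at most 0.5. Dntt was at 0.118 CPM in LT-HSC and 45.8 CPM in ST-HSC, Flt3 at 14.2 and 288 CPM, and Sema3d, Ighm, Atp8b4, Tespa1, Ccl3, BC035044, Slc9a9, Wfdc17, Itgb5 and Wfdc18 made up the other 10 highest genes. Cavin2 was 94.4-fold lower (40.1 to 292), Slamf1 17.4-fold (12.96 to 24.0), Sult1a1 12.9-fold and Nupr1 11.0-fold lower. Smtnl1, Meg3, Ncam2, Gda, Npas3, Clec1a, Fhl1 and Cracr2b made up the other lowest genes, with Meg3, an imprinted noncoding RNA, at 65.5 and 6.82 CPM. Hlf was 2.20-fold and Mecom 1.58-fold higher in ST-HSC, and Procr was at 81.3 and 62.1 CPM. The LT-HSC identity list stood at -0.35 (random range -0.22 to 0.23), with 22 of 43 members lower, and the HSC ageing list at -2.16 with 18 of 20 lower. The lymphoid progenitor list stood at 1.21 with 12 of 14 higher, and the immediate early list at -0.64 with 11 of 19 lower. The proteasome core list stood below its range at -0.39, with 14 of 23 lower, the G1 cyclin and CDK list on its bound at -0.42 and the ribosome biogenesis list on its bound at -0.23. The MHC class II and dendritic cell lists, both at 0.072, and the epigenetic list, at 0.25, lay inside.

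Within erythroid-like cells (mostly clusters 6 and 7 of LT-HSC against cluster 9 of ST-HSC) the ST-HSC cells held more haemoglobin RNA. Hbb-bs was at 3.47 CPM in LT-HSC and 397 CPM in ST-HSC, and Hba-a2, Hba-a1 and Hbb-bt were 121-fold, 74.3-fold and 35.9-fold higher, with Trim2, Sptb (beta spectrin of the red cell skeleton), Sh3tc2, Tmem56, Pkhd1l1, Mfhas1, Mgll and Plpp1 next. The erythroid list stood at 1.33 (random range -0.15 to 0.27), with 19 of 23 higher. Pf4 was 19.4-fold lower, Cd69 9.04-fold, Fos 7.34-fold and Cxcl10 6.79-fold lower, with Samd12, Ass1, Clec4d, Ier2, Pdzph1, Myct1, Cd9 and Nrgn next, and the immediate early list stood at -2.01 with 20 of 20 members lower. Inside cluster 9 alone Hbb-bs was at 6.60 CPM in LT-HSC and 449.6 CPM in ST-HSC, with a UMI in 34.4% of its cells, and the ST-HSC cells of clusters 6 and 7 stood at 3.34 and 4.40 CPM.

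Cycling cells, those with at least 1% of UMIs from cell cycle genes, were about as frequent in both libraries but of other kinds. They made 30.6% (28.8 to 32.4) of 2647 LT-HSC cells and 33.0% (31.8 to 34.2) of 5987 ST-HSC cells that reached 5000 UMIs, and 31.0% and 32.2% without thinning. With doublets kept in they made 30.7% (28.9 to 32.5) and 34.2% (33.0 to 35.4), with the intervals apart. At a limit of 2% the shares differed, with 2.04% (1.54 to 2.65) of LT-HSC and 4.99% (4.46 to 5.58) of ST-HSC. Of the LT-HSC cells, 16.2% lay near the limit of 1%, as did 13.1% of ST-HSC cells. Among cycling LT-HSC cells, 61.4% (58.0 to 64.8) were erythroid-like and 33.3% (30.01 to 36.6) megakaryocyte-progenitor-like, and 4.20% (2.93 to 5.82) HSC-like. Among cycling ST-HSC cells, 56.5% lay in the G2/M phase clusters, 21.7% in the S phase cluster and 14.0% in erythroid-like cells. The S phase list stood at 0.050 and the G2/M phase list at 0.17, both inside their ranges. In thinned cells the G2/M phase list stood above its range, at 0.30. Over all kept cells, 13 of 44 members of the S phase list and 22 of 52 of the G2/M phase list were higher. Kif23 and Ect2, needed for cell division, were 3.16-fold and 2.55-fold higher in ST-HSC, Hjurp 1.65-fold, Hells 1.95-fold, Brip1 1.94-fold, Uhrf1 1.94-fold and Pola1 1.71-fold, and Ube2c was at a ratio of 0.594. Without the erythroid-like and megakaryocyte-progenitor-like cells these lists stood at 0.78 and 2.08, both above their random ranges. That setting leaves out 497 and 269 of the 809 cycling LT-HSC cells but 276 and 6 of the 1976 cycling ST-HSC cells, which raises these lists by construction. Mki67, the proliferation marker, moved from 1.43-fold higher to a log2 ratio of 3.27, and Ube2c turned to higher, at 3.34, under the same exclusion. With HSC-like cells alone the S phase list stood below its range, at -0.60. The clustering sets cycling ST-HSC cells apart from that class, which holds 34 of the 809 cycling LT-HSC cells and 5 of the 1976 of ST-HSC, so it lowers the list by construction. There Hells (-0.57), Brip1 (-0.36), Uhrf1 (-0.36) and E2f2 (-0.65) turned to lower and Ube2c (1.12) to higher. The G1 cyclin and CDK list stood at -0.066, inside its range; Cdk6, a kinase that drives exit from quiescence, was 1.53-fold higher, E2f3 2.06-fold and E2f2 2.03-fold, while Myc and Mycn were at 113 and 58.6 and at 51.3 and 11.0 CPM.

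In cells with few cell cycle UMIs the lineage and gate genes still stood far apart. Among these 1888 LT-HSC and 4235 ST-HSC cells, 955 genes had a ratio of at least 2 and 418 of at most 0.5. Elane stood at a log2 ratio of 9.92, Flt3 at 5.44, Cd34 at 2.62, Hlf at 1.36 and Cdk6 at 0.58, and Slamf1 at -4.35, Pf4 at -4.79, Vwf at -3.24, Gata1 at -3.63 and Cdkn1c at -1.88. Hbb-bs, which stood at 3.48 in all kept cells, stood at -0.19, and Mki67 at -0.27.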

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

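The alternatives that leave out clusters, use the same doublet quantile in both libraries, or keep doublets for the cycling share were chosen after seeing the data. Of 508 list medians recomputed under the alternatives, 466 kept their side of the random range and 24 changed sign, 6 of these with the list outside its range before or after. Of 1844 recomputed ratios of 142 named genes, 980 stayed inside the counting interval, which is narrow at these depths, and 23 turned over. The mitochondrially encoded list ranged from 0.67 to 0.93, the megakaryocyte list from -2.01 to -0.68 and the lymphoid progenitor list from 1.21 to 2.70, always outside the random range. Depth limits genes with few UMIs in a library, such as Mpo in LT-HSC, and 1 library per group limits everything else. Where no construction shows it, the cause of a change was not tested.

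Without the erythroid-like and megakaryocyte-progenitor-like cells, 796 genes had a ratio of at least 2 and 625 of at most 0.5, and the lists stood at -0.98 for LT-HSC identity, -0.90 for Hox A and B, 0.78 for S phase, 2.08 for G2/M phase and 0.023 for ribosome biogenesis. That setting leaves nearly only HSC-like cells in LT-HSC but not in ST-HSC, which lowers genes of HSC-like cells by construction. There the log2 ratios turned over for Kit (-0.10), Clec4d (0.41), Kcng2 (0.36), Ube2c (3.34), Hbb-bs (-1.15), Hspa1b (0.86), Cycs (0.24), Psmb3 (0.0089), Hoxa7 (-0.15) and Hoxa9 (-0.11). With HSC-like cells alone, 629 genes had a ratio of at least 2, and the lists stood at -0.35 for LT-HSC identity, -0.60 for S phase and -0.43 for erythroid genes, the last on the bound of its random range. There Hells (-0.57), Brip1 (-0.36), Uhrf1 (-0.36), Ube2c (1.12), E2f2 (-0.65), Hbb-bs (-1.02), Cd74 (-0.42) and Pkm (-0.15) turned over, and Prss34, with 0 and 2 UMIs, gave no ratio. With cycling cells left out, LT-HSC identity stood at -0.26, S phase at -0.21 and G2/M phase at -0.22, outside their ranges, and Mki67 (-0.27) and Hbb-bs (-0.19) turned over; the removal of cycling cells lowers cell cycle genes by construction, and so do HSC-like cells alone in ST-HSC, while leaving out the erythroid-like and megakaryocyte-progenitor-like cells raises them. With all deposited barcodes, Hba-a2 (-1.61), Hba-a1 (-0.84) and Hbb-bs (-1.28) turned over. LT-HSC identity stood at -0.31 as the mean over cells and -0.30 in thinned cells, where G2/M phase stood at 0.30, all outside their ranges.

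Counts of genes followed the expression filter, which sets how many genes are tested. At least 1 CPM gave 1717 higher and 558 lower, at least 20 CPM gave 601 and 150, and no filter beyond 3 counts gave 3628 and 1716, with Hox A and B at -0.34.

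Shares of classes moved with the clustering. HSC-like cells in ST-HSC made 45.7% at resolution 0.4, 24.0% at 1.2, 32.5% without cell cycle genes, 20.8% with 15 components and 24.9% on thinned cells. In LT-HSC they made 37.5% at resolution 1.2, 35.7% with 15 components, 40.1% without ribosomal protein and mitochondrial genes, 36.9% with doublets kept in and 38.1% on thinned cells. Megakaryocyte-progenitor-like cells in LT-HSC made 28.8% at resolution 1.2, 29.7% with 15 components, 20% without ribosomal protein and mitochondrial genes and 29.7% with doublets kept in. In ST-HSC they made 0.512% with 15 components and 0.406% with doublets kept in. Lymphoid-progenitor-like cells in ST-HSC made 0% at resolution 0.4, 7.56% at 1.2, 16.03% without cell cycle genes, 7.41% with 15 components, 17.2% with doublets kept in, 16.7% on thinned cells and 16.3% with the same doublet quantile. Cycling shares of LT-HSC and ST-HSC were 51.8% and 51.8% at a limit of 0.5%, 2.04% and 4.99% at 2%, and 28.7% and 29.9% with the G2/M list alone. The ST-HSC share was 34.5% over all deposited barcodes and 34.2% with doublets kept in.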

Other observations

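All tests reported in this part were chosen after the results they bear on had been seen.

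Cd48, whose protein the LT-HSC gate excludes, was unevenly spread over the library labelled LT-HSC. It was at 3.54 CPM in HSC-like cells, 20.9 CPM in megakaryocyte-progenitor-like cells and 59.0 CPM in erythroid-like cells, where it was 16.7-fold higher (12.9 to 21.9) than in HSC-like cells. Flt3 was at 14.2 CPM in HSC-like LT-HSC cells and 288 CPM in HSC-like ST-HSC cells, and at 703 CPM in the lymphoid-progenitor-like cells of cluster 5. Cd34 was at 381 CPM in that cluster and at 3.82 CPM in the erythroid-like ST-HSC cells of cluster 9. Haemoglobin RNA was concentrated in barcodes with few genes or a high mitochondrial share, which were not kept: Hbb-bs made 25331 CPM of their UMIs in LT-HSC and 2382 CPM in ST-HSC.

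Little Slamf1 RNA and much Cd34 RNA in the library labelled ST-HSC set it apart from its stated gate. Flt3 RNA, which that gate does not mention, was high there as well. As far as RNA follows surface protein, an exchange of the labels is argued against by Flt3, whose protein only the LT-HSC gate excludes and which was 20.3-fold higher (17.8 to 23.2) within HSC-like cells labelled ST-HSC. Cells of the other named classes mixed into the library are argued against for Slamf1 and Flt3 but stay open for Cd34. Cells of other types inside the HSC-like class stay open for each of these genes. At resolution 0.4 HSC-like cells made 45.7% of ST-HSC and lymphoid-progenitor-like cells 0%, so the line between these classes was not fixed. The Slamf1 ratio was 0.0574 (0.0418 to 0.0772) within HSC-like cells. Inside clusters 1 and 3 it was 0.0717 (0.0334 to 0.176) and 0.151 (0.0182 to 0.546). Flt3 was 10.7-fold (5.20 to 26.7) and 4.73-fold (2.91 to 7.34) higher there. These rest on few UMIs, with 8 of Slamf1 and 7 of Flt3 in LT-HSC cells of cluster 1, and 2 and 22 in ST-HSC cells of cluster 3. Cd34 was 3.57-fold higher (3.36 to 3.80) within HSC-like cells, mostly cluster 3 against cluster 1, but at ratios of 1.51 (1.12 to 2.07) inside cluster 1 and 1.06 (0.681 to 1.57) inside cluster 3. Another gate than the one stated, or RNA that departs from surface protein, may account for the pattern and cannot be told apart, because no protein was measured, and a difference between LT-HSCs and ST-HSCs stays open and untested.

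Erythroid-like and megakaryocyte-progenitor-like cells made up much of a library sorted as LT-HSC. Free RNA spread evenly over droplets is argued against only by how low their markers stood in HSC-like LT-HSC cells. The markers were at a median of 0.0596 of the level in the cells named after them (Car1 39.0 against 6190 CPM, Pf4 71.5 against 2808 CPM). The classes were named by these same markers, so a level below that of the named cells was set by the naming, but not how far below. As the source of the erythroid-like class, droplets holding an HSC and an erythroid cell are argued against. HSC markers there stood at a median of 0.0573 of the HSC-like level. Droplets holding an HSC and a megakaryocyte progenitor are argued against by 5 of 14 HSC markers that lay under 0.25 of that level. Among these were Procr at 0.0698 and Hlf at 0.164, although the median of the 14 was 0.284. The HSC-like clusters were named by the HSC markers, so a level below theirs was set by the naming, but not how far below. Cells from outside the gate could be a source: Ly6a stood at 0.307 of the HSC-like level in erythroid-like cells and 0.373 in megakaryocyte-progenitor-like cells, and Slamf1 at 0.377 and 0.888. Ly6a and Slamf1 leave it open, since at most 0.25 for both genes would mark such cells and at least 0.5 cells inside the gate. Only Slamf1 in megakaryocyte-progenitor-like cells passed either limit. Both limits were set on shares of RNA, while a sort reads the amount on each cell. Median UMIs per LT-HSC cell were 11983 in HSC-like, 30703.5 in erythroid-like and 21653 in megakaryocyte-progenitor-like cells. Ratios per cell would thus be higher for both genes, and the limits cannot settle the question. Cd48 was no part of that rule. It was at 16.7-fold (12.9 to 21.9) the HSC-like level in erythroid-like cells and 5.92-fold (4.48 to 7.93) in megakaryocyte-progenitor-like cells. That is the direction of cells from outside a gate that excludes CD48, as far as RNA follows surface protein. Stem cells with early erythroid and megakaryocyte RNA stay open as well.

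Mitochondrially encoded RNA was higher in the library labelled ST-HSC. Another mix of classes is argued against by a median log2 ratio of 0.76 within HSC-like cells and 1.09 within erythroid-like cells, both above random lists. The mix within a class was not held fixed, since these compare mostly cluster 3 with 1, and 6 and 7 with 9. The median mitochondrial share was higher in ST-HSC inside each of these clusters. It was 1.83% in LT-HSC and 3.596% in 43 ST-HSC cells of cluster 3, and 1.38% and 3.09% in cluster 6. In cluster 1 the gap was small, at 3.14% in 27 LT-HSC cells and 3.61% in ST-HSC. A fraction of damaged cells is argued against by the 10th percentile of the mitochondrial share over ST-HSC cells, 2.67%, which lay above the LT-HSC median of 1.60%. Handling or sequencing of one whole library may be the cause, and cannot be told apart from a difference between the populations, since each group is 1 library and the classes held by both moved up, by 1.09 in erythroid-like cells.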
